A study of Mus musculus with 2 samples.

How the data were processed

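Total RNA of C3H10T1/2 mouse cells, kept with BMP7 at 3.3 nM or with vehicle over 3 days, was measured on 2 miRNA arrays, 1 per group, per the labels. Per the labels' protocols, RNA was taken up in Qiazol, 5 micrograms were given a poly(A) tail, and the RNA was labelled with Cy3 with the mirVana kit. Cy3 is read at 532 nm, called the Cy3 channel below. What the second channel of the same scans, at 635 nm, holds is not given in the sources used here, so the arrays were treated as having 1 colour.

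Per the file headers, the scanner exports come from GenePix with no normalization, and their intensity columns are mean spot brightness at each wavelength with the local background not subtracted. Detector gain was equal on both arrays (720 at 635 nm and 580 at 532 nm), but the laser power reading at 532 nm was 3.17 for the BMP7 array and 2.45 for the vehicle array. The exports also hold, per the file headers, the sum over both wavelengths of the background-subtracted means and their ratio, which can be negative and was used as a score. From these 2 columns the local background at 532 nm was solved for 1723 and 1727 of the 1728 spots on the BMP7 and vehicle arrays, and the other 5 and 1 took the median of their block. The authors' deposited table and the matrix of values hold the same ratio values. For array probes these were rebuilt as the mean over 4 spots of the 532 nm over the 635 nm brightness, divided by the same mean for spots named Control_1, with no background subtraction. This gave the deposited value within 0.1% for 336 of 339 probes on the BMP7 array and 337 of 339 on the vehicle array. The column medians were 0.0813 and 0.0539. For the 16 rows of a customized panel the scale, reference and assay stay unknown.

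The 532 nm intensity was background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, fitted on all spots. Control spots were then removed, both arrays were quantile normalized, and the log2 values of the 4 spots were averaged. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Probe names carry human, mouse or rat prefixes of an old design. They were matched by name to the mouse miRNA genes of an NCBI RefSeq table (assembly GRCm38.p6), which was used for names and for neighbouring genes only; the build behind the array is not given in the sources used here, so no coordinates are printed. Of 377 probes, 279 matched a mouse miRNA, and 256 were kept with 1 probe each (201 with a human, 49 with a mouse and 6 with a rat prefix), 255 of them with a gene in that table. The remainder were 23 second probes, 65 probes with no mouse gene of that name and 33 of the array maker's own. Mature miRNAs of one family differ by few bases, and a probe can read its relatives.

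The detection rule fixed in advance asked for 2 standard deviations of a spot's own background, which the exports do not give. In its place, a spot passed when it exceeded its local background by 2 standard deviations of the local backgrounds over the array (948 units for BMP7 and 1152 for vehicle), and a miRNA was detected when at least 2 of 4 spots passed. A miRNA detected on 1 array only is given as a bound when it is named, and with no fold where that bound is not above 1. Counts and list medians use the fitted values, and an alternative puts such miRNAs at their bounds, or at 0 where there is none.

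The design was fixed before the data were examined: counts of miRNAs at a 2-fold change, the median of 26 miRNA lists from general knowledge, and the agreement of both arrays, with no test across samples because each group has 1 array. The rule for naming took, among detected miRNAs, up to 12 per direction with a change of at least 2-fold and every BMP7 spot on one side of every vehicle spot, 12 miRNAs fixed by name, and, for lists with at least 3 detected members, the 2 members of largest increase and the 2 of largest decrease. Lists with fewer are given by their members' values. A list's percentile comes from 10000 random lists of the same size drawn within 3 classes of mean level, and describes these arrays only.

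The steps were tested on simulated data. Here 2 arrays were drawn from the vehicle array, with 20 of 58 detected miRNAs changed by 1.5 on the log2 scale. Normexp with quantile normalization gave the right sign for 19, put 10 past 2-fold and fitted a median of 0.99, so folds were understated there. Both simulated arrays had the vehicle background, while the real arrays differ in background (medians of 4650 for BMP7 and 3756 for vehicle). The simulation therefore does not show how unequal backgrounds act on the folds. The brightest changed miRNA was fitted at 0, because quantile normalization gives the brightest probe of each array the same value, and unchanged miRNAs reached 0.60. With median scaling the right sign came out for 20, with 12 past 2-fold. On the real arrays let-7c on vehicle and miR-140_AS on BMP7 hold that top place, and median scaling gave them -1.00 and 1.06. For lists, 1 of 100 simulated lists without a shift lay above the upper percentile used for calling a list apart, and 67 of 100 with a shift of 0.6 did. These lists had 8 members with independent values. The rate for lists of other sizes, or with members that share genes or probe signal, was not tested.

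Alternatives were other scalings, other background corrections, other detection rules and thresholds, the median of spots, leaving out each of the 4 spots in turn, and the authors' own table. Some were added after the data had been seen, as the closing section says.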

Results

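C3H10T1/2 is a mouse mesenchymal cell line that can be led toward fat, bone or cartilage cells, and BMP7 is a bone morphogenetic protein, a secreted growth factor that signals through SMAD proteins. The study asked which miRNAs BMP7 regulates in this line. Cells given BMP7 at 3.3 nM were compared with cells given vehicle, after 3 days. Total RNA of each was labelled with Cy3, a fluorescent dye, and put on 1 array per group, so the difference between the groups has no replicate check, no p-value is given, and the number of arrays limits the precision. Errors below are standard errors over the 4 spots of a probe (n = 4 on each array), which cover the spread within an array and not that between cultures. They take the spots as independent and do not pair them by place between the arrays. Each array held 377 probes other than controls, of which 256 were kept as mouse miRNAs with 1 probe each. The Cy3 signal stood low over its surroundings: the median local background of the Cy3 channel was 4650 intensity units on the BMP7 array and 3756 on the vehicle array, and 63.9% and 44.5% of the spots lay below it. Of the 256 mouse miRNAs, 41 were detected on the BMP7 array and 58 on the vehicle array. The comparison took the 65 detected on 1 or both arrays, of which 34 were detected on both. Among 65 probes for miRNAs with no mouse gene of that name, 7 (10.8%) passed the same rule, against 25.4% of the mouse miRNAs.

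With quantile normalization, the miRNAs at least 2-fold higher with BMP7 and with every BMP7 spot above every vehicle spot were miR-22 and miR-223. Their rank depends on the scaling: with cyclic loess miR-140_AS was at 1.26, miR-22 at 1.12 and miR-223 at 1.04. MiR-22 was 2.18-fold higher (log2 change 1.12 ± 0.13) and miR-223, best known from myeloid blood cells, was 2.01-fold higher (1.01 ± 0.12). Both fell under 2-fold in some alternatives: with no background correction miR-22 was at 0.82 and miR-223 at 0.52, and in the authors' deposited table they were at 0.92 and 0.22. The log2 folds of that table are not centred on 0, and their median over its 339 array probes was 0.54. In the second channel miR-223 was also brighter with BMP7 (mean 819 against 533), while miR-22 was not (5224 against 5387). Among miRNAs detected on both arrays, the largest lower values belonged to the let-7 family, miRNAs that accumulate as cells differentiate: let-7e was 2.34-fold lower (log2 change -1.23 ± 0.10) and let-7c was 2.04-fold lower (-1.03 ± 0.11). With no background correction they were at -0.92 and -0.80, and let-7c was at -0.85 with cyclic loess. In the authors' deposited table let-7c was at -0.023, and let-7e, which that table holds only in a separate panel described below, was at 0.14. MiR-503 was at least 2.16-fold lower, given as a bound since it was not well above background on the BMP7 array. It was at -0.50 on the log2 scale with no background correction, -0.87 with scaling on the Cy3 control spots and 0.076 in the authors' deposited table. MiR-190 and miR-494 were not well above background there either, and were at least 1.02-fold and at least 1.13-fold lower. MiR-494 was at 0.59 in the authors' deposited table. In the second channel miR-494 was dimmer with BMP7 as well (mean 7590.5 against 12854.5), and miR-190 was not (202.5 against 188.75). An "at least" bound sets the brighter array's mean against the higher of the dim probe's own value and the lowest value among detected miRNAs, and covers neither the spread of the spots nor the choice of processing.

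**Figure D1:**
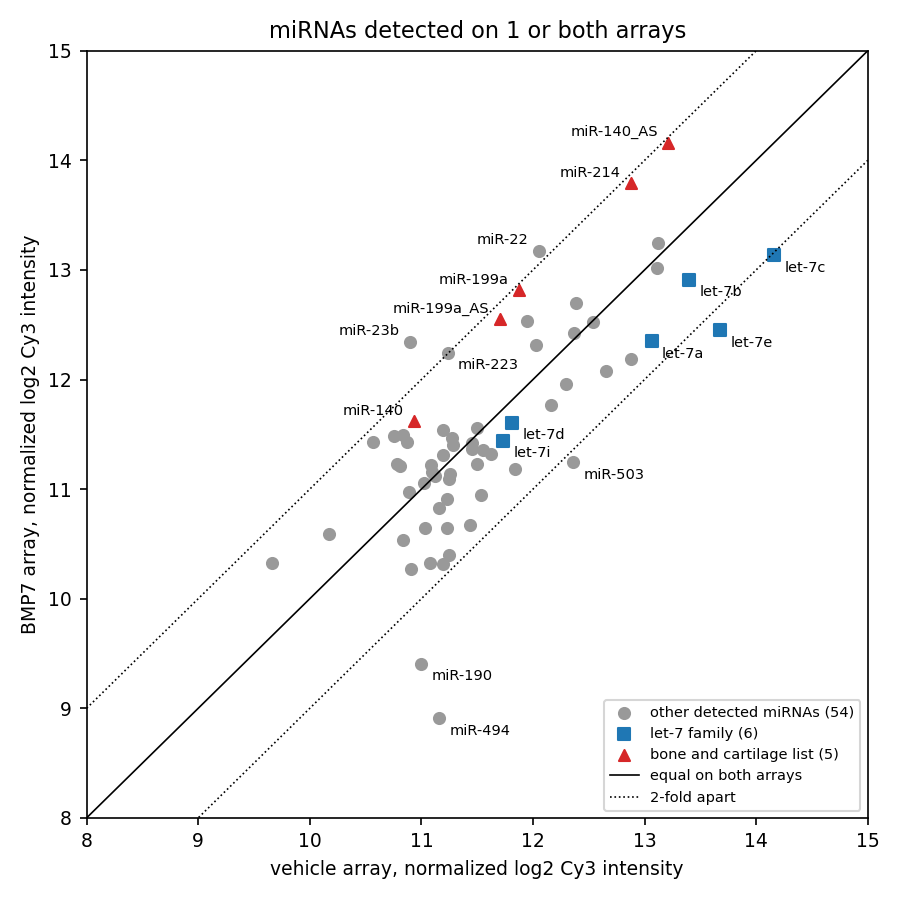
Normalized log2 Cy3 intensity of the 65 detected miRNAs on the vehicle array (x axis) and the BMP7 array (y axis), 1 point per miRNA, with a solid line for equal values and dotted lines for a 2-fold difference. The 6 let-7 points lie below the solid line and the 5 points of the bone and cartilage list lie above it, close to the upper dotted line.

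In all, by fitted values, 3 miRNAs were at least 2-fold higher and 5 at least 2-fold lower with BMP7. With the 31 miRNAs detected on 1 array put at their bounds, 3 were higher and 3 lower. The split was 1 higher and 10 lower with 75th percentile scaling, 7 higher and 3 lower with scaling on the Cy3 control spots, and 1 higher and 6 lower with no normalization between arrays. It was 0 and 0 with no background correction, and 15 higher and 20 lower with plain subtraction. The remaining miRNA among the 3 was miR-23b, with a log2 change of 1.45 ± 1.02, whose vehicle spots had an SD of 2.02 and overlapped the BMP7 spots. In the authors' deposited table its log2 fold was -0.72. Every BMP7 spot lay above every vehicle spot for 12 miRNAs and below for 15, while for 38 the spots overlapped. Spots of equal arrays would stand apart in this way for 2.86% of miRNAs if the 4 spots varied independently. They did not always: on the vehicle array let-7i was at 10.84 and 11.21 in spots 1 and 2, and at 12.38 and 12.50 in spots 3 and 4. The share for spots linked in this way is not known, and any difference between 2 arrays, BMP7 aside, also sets spots apart. Across the 65 miRNAs, which are not independent replicates, the levels on both arrays had a Pearson r of 0.73 and a Spearman rho of 0.69.

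Of the 12 probes of the bone and cartilage list on the array, 5 were detected. These 5 were all higher with BMP7, and for all 5 every BMP7 spot lay above every vehicle spot. They were both strands of miR-140, a cartilage miRNA, both strands of miR-199a, and miR-214, whose gene neighbours a miR-199a gene. MiR-140_AS had a log2 change of 0.95 ± 0.21 and miR-199a one of 0.94 ± 0.18. The other members, named after their values were seen, were at 0.91 ± 0.06 for miR-214, 0.85 ± 0.20 for miR-199a_AS and 0.69 ± 0.21 for miR-140. The list's median of 0.91 lay at percentile 97.8 of 10000 random lists of the same size and similar levels. The random lists hold miRNAs drawn singly, while strands of one miRNA and neighbouring genes may vary together. The percentile may therefore overstate how far this list stands apart. The list shares both miR-199a strands with the SMAD-processed list, miRNAs whose maturation SMAD proteins are known to aid, which had a median of 0.85 at percentile 95.7. In that list, 4 of the 5 detected members had every BMP7 spot above every vehicle spot, including miR-21 at 0.31 ± 0.12 and miR-23a at 0.29 ± 0.08. Its member of largest value was miR-23b, and without it the median was 0.58; with no background correction the median was 0.16.

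All 6 detected members of the let-7 and miR-98 family had negative values, with a median of -0.60 at percentile 1.0 and a mean of -0.66. Probes of this family may read each other's miRNAs, which the percentile does not take into account. For 4 of them, every BMP7 spot lay below every vehicle spot. Besides let-7e and let-7c these were let-7a at -0.71 ± 0.12 and let-7b at -0.49 ± 0.16, named after their values were seen, while let-7d at -0.21 ± 0.09 and let-7i at -0.29 ± 0.51 had overlapping spots. In the authors' deposited table, which holds 5 of these 6 on the array, let-7a was at 0.16 and let-7d at 0.24, the median was -0.023 on the log2 scale, and the median of all its rows was 0.54. These 2 lists lay furthest from the middle of the random lists among the 10 lists with at least 3 detected members.

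**Figure D2:**
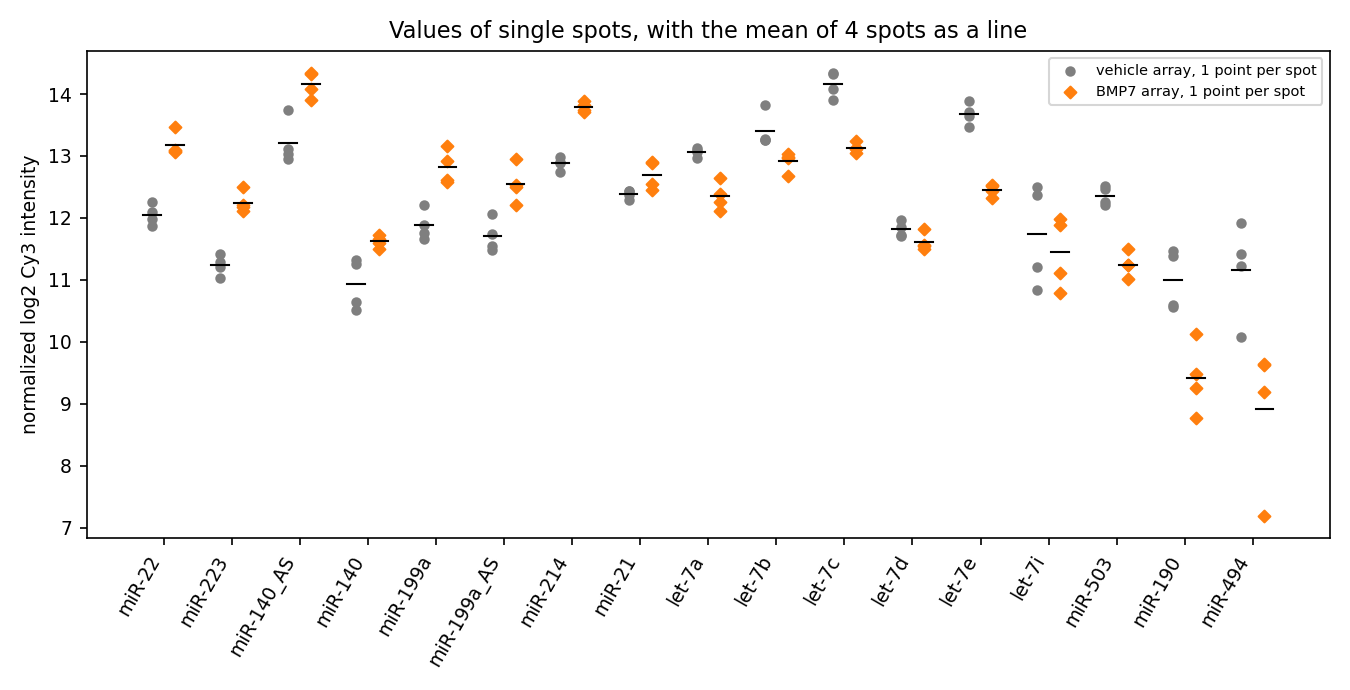
Normalized log2 Cy3 intensity (y axis) of single spots for 17 miRNAs (x axis), circles for the vehicle array, diamonds for the BMP7 array, and a line at the mean of 4 spots. The BMP7 spots of let-7e lie wholly below its vehicle spots and those of miR-214 wholly above, while those of let-7i overlap.

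MiRNAs known to restrain adipogenesis had a median of -0.25 over 14 detected members, at percentile 6.7. This list holds the 6 let-7 members, and miR-22 and miR-221 lay on the other side; miR-221 was at least 1.83-fold higher. In the authors' deposited table the median of its 13 members there was 0.35, beside 0.54 over all array probes of that table. MiRNAs known to promote adipogenesis had a median of 0.00 over 7 detected members (percentile 58.9), with miR-30a-5p at least 1.66-fold higher and miR-92 at least 1.58-fold higher, and only 2 of the 7 were detected on both arrays. For miR-30a-3p no direction is given: it was detected on the vehicle array only, its spots overlapped, and the sign of its log2 change turned without 1 of them (0.07) and in the authors' deposited table (0.57). Of the list that promotes brown and beige adipogenesis, 3 members were detected: miR-378 at least 1.36-fold higher but with overlapping spots, miR-328 at 0.20 ± 0.18 and miR-26a at -0.40 ± 0.08, which gave a median of 0.20 (percentile 76.7). With plain subtraction and median scaling miR-378 was at -0.51 and the median at -0.27, and miR-26a was at 0.56 in the authors' deposited table. Of the list that restrains it, 4 were detected with a median of 0.08 (percentile 63.3) and a mean of -0.00054, so that median and mean differ in sign.

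Among the families, the miR-99, miR-100 and miR-125 list had a median of -0.29 (percentile 16.4), with miR-99a at -0.34 ± 0.14, miR-99b at -0.30 ± 0.12 and miR-125b at 0.06 ± 0.13. In the authors' deposited table the median was 0.38, with miR-99a at 0.18 and miR-99b at 0.57, beside 0.54 over all array probes of that table. The miR-15 and miR-16 family had a median of 0.09 over 3 members (percentile 72.5), but -0.12 with 75th percentile scaling, -0.79 with plain subtraction and -1.54 with that and median scaling. The list of miR-23, miR-24 and miR-27 had a median of 0.20 over 4 members (percentile 71.6). With fewer detected members, the miR-17 clusters gave miR-92, at its bound above, and miR-93 at 0.12, and of the miR-221 and miR-222 pair, miR-222 was at 0.05. The miR-181 family gave miR-181b, detected on the vehicle array only and with no fold given. MiR-145 was at -0.57 ± 0.05, but at 0.72 in the authors' deposited table, and miR-143, from the same cluster, was detected on the vehicle array only, with no fold given. The miR-30 family gave its 2 miR-30a strands, and the Dlk1-Dio3 cluster gave miR-494 and miR-337, the latter detected on the vehicle array only, with no fold given. No member of the miR-29 family, of the miR-193b and miR-365 cluster or of the hypoxia and stress list was detected.

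Markers of other cell types gave few detected probes. Of 6 blood cell probes only miR-223 was detected, and miR-142, miR-144, miR-150 and miR-155 were not. Muscle gave miR-499, at least 1.32-fold higher but with overlapping spots, and liver and gut gave miR-192, at least 1.20-fold lower. Epithelium gave miR-141, detected on the vehicle array only, with no fold given. The pluripotent cell list gave miR-290, at least 1.04-fold lower with overlapping spots, and miR-291-5p, at least 1.38-fold lower. In the authors' deposited table these signs were turned: miR-499 was at -0.066, the mouse probe of miR-192 at 0.24, miR-290 at 0.49 and miR-291-5p at 0.073. For miR-192, miR-290 and miR-291-5p that holds against 0 only. Against the median of 0.54 over all array probes of that table they were lower, their direction in the Cy3 channel. The neuron and endothelium lists gave no detected probe.

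Of 12 miRNAs fixed by name because of work on adipogenesis, 10 had probes on the array. Only miR-21 and miR-143 were detected, while miR-193b, miR-365, both strands of miR-182, miR-203, miR-133a, miR-196a, miR-27b and miR-30c were not well above background on either array, and no fold is given for them. MiR-455, known from work on BMP7 and brown fat, was not among the array's probes. It was listed in the authors' deposited table in a separate customized panel of 16 miRNAs, whose assay, scale and reference are not given in the sources used here. There it was 1.67-fold higher with BMP7, as a single value per group with no error. In the same panel of the authors' deposited table, the muscle miRNAs were lower with BMP7: miR-206 by 3.60-fold, miR-1 by 3.32-fold, miR-133a by 2.97-fold and miR-133b by 1.58-fold. Their deposited levels were low, between 9.7e-12 and 2.1e-09 on that panel's unstated scale, against 0.0017 for miR-455 with BMP7. Lower values there were not limited to muscle miRNAs. In that panel of the authors' deposited table miR-709 was 2.95-fold, miR-181a 2.77-fold and miR-125a-5p 2.30-fold lower with BMP7. Their deposited levels with vehicle were higher, at 1.2e-05, 4.2e-07 and 9.3e-07. On the array, miR-206, miR-1 and miR-133a were not detected. MiR-205 was 2.13-fold higher and miR-379 2.02-fold higher in that panel of the authors' deposited table, and 7 of its 16 miRNAs were higher and 9 lower. The deposited levels with BMP7 were also low for these, at 8.7e-10 for miR-205 and 4.7e-09 for miR-379, and neither was detected on the array. Let-7e was 1.11-fold higher in the panel, at a low deposited level (1.5e-08 with BMP7 and 1.4e-08 with vehicle), against 2.34-fold lower on the array. MiR-98, listed in the same family, was 1.12-fold higher in that panel of the authors' deposited table. Its deposited level was higher (3.4e-04 with BMP7 and 3.0e-04 with vehicle), and it was not detected on the array.

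**Figure D3:**
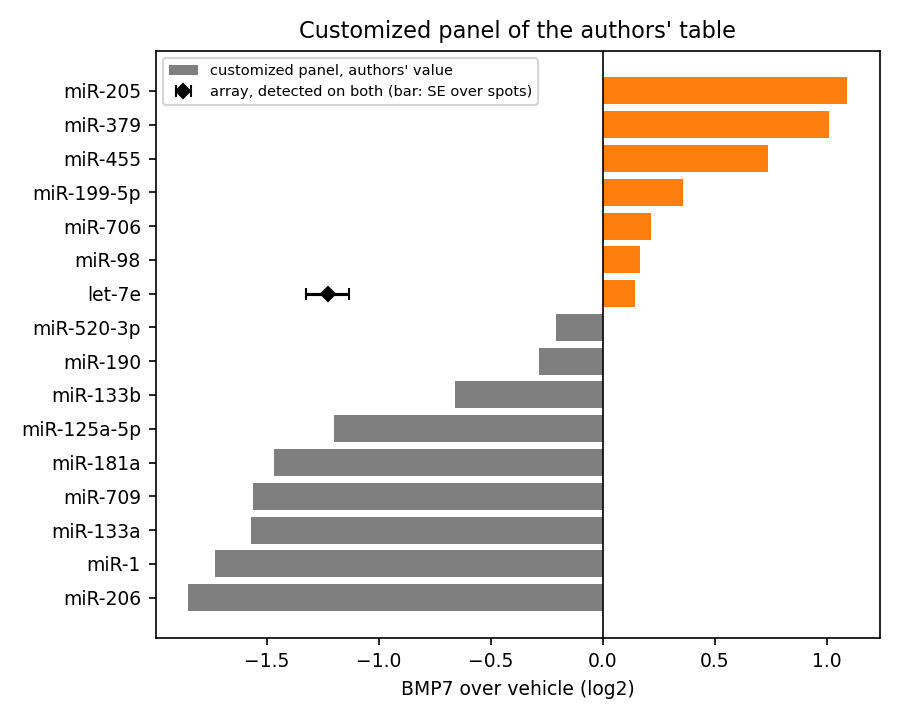
Log2 of the fold of BMP7 over vehicle (x axis) for the 16 miRNAs of the customized panel (y axis), as bars of the authors' deposited values, with a diamond for the array's own value of let-7e, detected on both arrays (error bar, standard error over spots). MiR-205 has the highest bar and miR-206 the lowest, and let-7e has values on both sides of 0.

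The authors' deposited table gives 339 array probes as a ratio that sets the Cy3 brightness against that of the second channel of the scans, whose content is not given in the sources used here. In it 314 of the 339 (92.6%) were higher with BMP7, with a median fold of 1.46. It lists 26 probes as at least 2-fold higher, of which 24 were not detected in the Cy3 channel, and 1 as at least 2-fold lower. Among the 64 detected miRNAs that this table holds, 25 were higher with BMP7 in the authors' deposited table and lower after background correction of the Cy3 channel. MiR-503 and miR-494 were among these 25. Taken against the deposited median of all 339 probes, 39 of the 64 had the same sign as in the Cy3 channel.

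**Figure D4:**
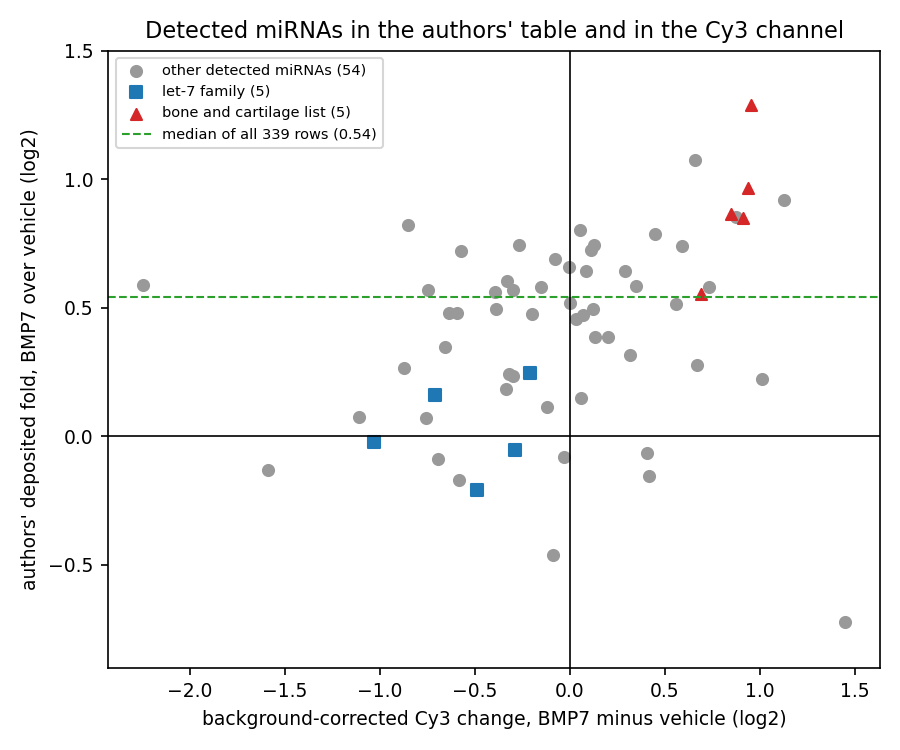
Log2 of the authors' deposited fold of BMP7 over vehicle (y axis) against the background-corrected log2 change of the Cy3 channel (x axis) for 64 detected miRNAs, with a dashed line at the median of all 339 rows. Most points lie above 0 on the y axis, and the 5 let-7 points lie below the dashed line.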

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

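The values in this part were not chosen in advance; they come from data outside the comparison of the groups. In the second channel, whose content is not given in the sources used here, 340 of the 377 probes were brighter than the brightest Control_1 spot on both arrays, and the values of the probes in that channel had a Spearman correlation of 0.99 between the arrays.

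Of the 33 probes of the array maker's own, 4 were detected on both arrays. Probe ambi_miR_7038_1 had a log2 change, BMP7 minus vehicle, of 0.70, and ambi_miR_7081 one of -0.71, each with every BMP7 spot on one side of every vehicle spot. Probe ambi_miR_7070 was at 0.20 and ambi_miR_7103 at 0.18, with overlapping spots. Of the 65 probes for miRNAs with no mouse gene of that name, 7 passed the detection rule on at least 1 array.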

How the results depend on the processing

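Tests added after the data had been seen were plain subtraction joined with median scaling, miRNAs detected on 1 array at their bounds, detection above probes with no mouse gene, the 2-fold counts limited to miRNAs whose spots stand apart (the naming rule had asked for this in advance), and lists without their member of largest change. No analysis paired by sample was possible because each group has 1 array, and spots were not paired by their place on the arrays. The signal stood low over its background, which limits detection and, in simulated arrays of equal background, understated folds. The cause of the shifts below was not tested. Among the named miRNAs, 457 of 499 alternative values kept their sign, and among the list medians 178 of 200. The let-7 median stayed below 0 and the bone and cartilage and SMAD-processed medians above 0 in all 20 alternatives run for each. The median change of all detected miRNAs was -0.03, and was -0.25 with 75th percentile scaling, -0.18 with no normalization, -0.13 with cyclic loess, 0.13 with Cy3 control scaling and -0.37 with plain subtraction.

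With 75th percentile scaling, 1 miRNA was at least 2-fold higher and 10 lower, and the medians were 0.63 for bone and cartilage and also 0.63 for SMAD-processed, -1.05 for let-7, -0.63 for restraining adipogenesis, -0.12 for miR-15 and miR-16, 0.064 for miR-23, miR-24 and miR-27, and -0.46 for miR-99, miR-100 and miR-125. Median scaling put let-7 at -0.80. With no normalization, 1 was higher, and the medians were 0.70 for bone and cartilage, -0.98 for let-7 and -0.56 for restraining adipogenesis. Scaling on Cy3 control spots gave 7 higher and 3 lower, and medians of 1.01 for bone and cartilage, 0.27 for miR-15 and miR-16, 0.45 for miR-23, miR-24 and miR-27, and -0.079 for miR-99, miR-100 and miR-125.

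With no background correction, 0 were higher and 0 lower by 2-fold, and the medians were 0.67 for bone and cartilage, 0.16 for SMAD-processed and -0.070 for miR-99, miR-100 and miR-125. Plain subtraction with a floor of 1 gave 15 higher and 20 lower, r = 0.64, and medians of 1.28 for bone and cartilage and also 1.28 for SMAD-processed, 0.40 for promoting and -0.45 for restraining adipogenesis, -0.79 for miR-15 and miR-16, 0.35 for miR-23, miR-24 and miR-27, and -0.57 for miR-99, miR-100 and miR-125. Joined with median scaling it gave 13 higher and 20 lower, and medians of 1.54 for bone and cartilage and also 1.54 for SMAD-processed, 0.35 for promoting adipogenesis, -0.27 for promoting brown and beige adipogenesis, -1.54 for miR-15 and miR-16, and 0.63 for miR-23, miR-24 and miR-27.

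With no filter on detection, 15 were higher and 15 lower, with medians of 0.77 for bone and cartilage and 0.32 for SMAD-processed. With miRNAs detected on 1 array at their bounds, 3 were lower and no list median moved. Among miRNAs detected on both arrays, 2 were lower, and miR-15 and miR-16 had a median of 0.34; detection above probes with no mouse gene gave 0.33 there. At 1.5-fold, 13 were higher and 14 lower, and at 3-fold 0 and 2. The BMP7 array had 27 detected miRNAs at 3 background SDs, 122 above the 95th percentile of Control_1 spots and 24 when all spots had to pass, and the vehicle array had 37 at 3 SDs and 29 when all had to pass. The median of spots gave 0.64 for SMAD-processed, and without miR-23b it was 0.58. Leaving out each spot in turn put SMAD-processed between 0.45 and 0.91, and promoting adipogenesis between 0.070 and 0.249.

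Among the detected miRNAs, the authors' own table gave 0 lower by 2-fold and r = 0.97. This r does not show closer agreement of miRNA levels. Over the 339 array probes, the deposited values had a Spearman correlation of -0.95 with the second channel on each array. With the Cy3 brightness it was 0.02 for BMP7 and 0.07 for vehicle. The second channel itself was nearly the same on both arrays (Spearman 0.99). Signs that the authors' table turned included those of miR-503 to 0.076, miR-494 to 0.59, miR-26a to 0.56, miR-99a to 0.18, miR-99b to 0.57, miR-107 to 0.58, miR-30a-3p to 0.57, miR-24 to 0.66 and miR-23b to -0.72. Of these, miR-503 and miR-99a still lay below the median of all its rows. Its medians were -0.023 for let-7, 0.64 for SMAD-processed, 0.58 for promoting and 0.35 for restraining adipogenesis, 0.64 for miR-15 and miR-16, 0.65 for miR-23, miR-24 and miR-27, and 0.38 for miR-99, miR-100 and miR-125, each beside a median of 0.54 over all its rows.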

Other observations

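In this part, the tests of spotted probe and of variation between arrays were set before their results were seen, and all other tests were chosen only afterwards. The miRNAs and gene clusters named here for the first time were chosen after their values were seen.

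The genes of miR-503, miR-351 and miR-322 lie beside each other in the mouse annotation. MiR-503 was at least 2.16-fold lower with BMP7 (a log2 change of -0.50 with no background correction and 0.076 in the authors' deposited table) and miR-351 was 1.62-fold lower (log2 change -0.69 ± 0.14, standard error over spots, and -0.089 in that table), each with every BMP7 spot below every vehicle spot. The probe named miR-322 was not detected on either array, but old probe names were matched by name only. Members of the let-7 family share gene clusters with miR-99 and miR-125, and the 2 groups of miRNAs differed in their values, as described below.

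The let-7 list was lower and the bone and cartilage list higher on the BMP7 array. A constant factor in brightness moves both lists alike; against one that depends on the level, the bone and cartilage median stayed above the let-7 median by at least 1.08 (log2) in the 5 corrections that act by level. More or less spotted probe on one array would show in both channels, if the second channel reads the spotted probe, which no source states. The difference there was 0.27 ± 0.04, against 1.51 in the Cy3 channel. Taken singly, the let-7 median in the second channel was -0.37 and the bone and cartilage median -0.09, beside -0.14 over the authors' array probes. Let-7e and let-7c were dimmer there with BMP7 (mean brightness 4452 against 6860, and 6384 against 9456), the same direction as in the Cy3 channel. Variation between arrays or cultures unrelated to BMP7 cannot be told apart from an effect of BMP7, because there is 1 array per group. An opposite response of these lists to BMP7 therefore stays an untested hypothesis.

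Let-7 members were lower by more than the other miRNAs of their gene clusters. In all 5 pairs of a detected let-7 member (let-7a, let-7c or let-7e) and a detected miRNA whose gene lies within 50000 bp (miR-99a, miR-99b, miR-125a or miR-125b), the partner's log2 change lay above that of let-7, by at least 0.69. A lower output of the shared clusters would move both alike, which stays open: a miRNA of 3 pairs has more than 1 gene, and let-7 probes may read other members. The background may compress the change of the dimmer partners, but with it subtracted and median scaling, the difference stayed at 0.53 or more in the 4 pairs detected on both arrays (2.1 to 9.0 standard errors over spots, which omit variation between arrays), while for let-7e and miR-125a it was 0.42 and compression stays open. Let-7 probes may also read other family members: let-7e lay below the lowest other let-7 probe by a difference of -0.20 ± 0.15, which leaves this open. In the customized panel of the authors' deposited table let-7e was 1.11-fold higher, at a low level (1.5e-08 with BMP7) on an unstated scale. Its partner there, miR-125a-5p, was 2.30-fold lower, the reverse of the order on the array. Among the array probes of that table, let-7a (0.16) was not below miR-125b (0.15). Let-7c (-0.023) was below both miR-125b and miR-99a (0.18).

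Most probes were higher with BMP7 in the authors' deposited table, with a median log2 fold of 0.54. The Cy3 brightness alone gave a median of 0.14, so that most of the excess is consistent with the division by the brightness of the second channel, whose own median log2 fold was -0.14, and by the Control_1 spots, whose ratio was 17.5 on the BMP7 array and 20.5 on the vehicle array. A general rise of miRNAs would put detected miRNAs at or above the deposited median, if both scans were equally bright. Their background-corrected and unscaled median was -0.18 ± 0.11. It was 0.13 with scaling on the Cy3 control spots, which were dimmer on the BMP7 array (median 29939.5 against 35681.5). Both values lie below 0.54, but that median covers all 339 probes and not only detected ones. With 1 scan per group, a general rise is not settled by these values. The laser power for Cy3 differed between the scans, and whether it moved these values was not tested.

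Single bright spots stood out in 2 miRNAs of the authors' deposited table. MiR-323 has the highest deposited fold, 4.45. Its BMP7 spots in the Cy3 channel included one of 14071 beside others of 2583 to 4405. The fold rebuilt from all spots was 16.7 but 4.46 without that spot, so that the deposited value does not hold it. The other BMP7 spots overlapped the vehicle spots in the Cy3 channel (2988 to 3895). In the second channel they were dimmer (887 to 3725) than the vehicle spots (5091 to 6692), so that the remaining fold lies in the divisor. MiR-301, the only array probe at least 2-fold lower there, had a vehicle spot of 14212 beside others of 3332 to 3451; vehicle over BMP7 was 3.13 with it and 0.70 without it.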
